A study of Kluyveromyces marxianus and Kluyveromyces lactis with 30 samples.

How the data were processed

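The 30 libraries were poly(A)-captured RNA of K. marxianus Km31 and K. lactis yLB72, per the labels' protocols from cultures back-diluted to an optical density of 0.05 in 50 mL and collected at a density of 0.4 to 0.85. The labels give 28C for the controls and 39C for heat, and no dose for MMS, ethanol or caffeine. Groups and replicate numbers came from the sample titles. The series describes the replicates as biological.

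The deposited values are raw counts per feature, with no normalization by the authors. The submitters' processing notes name TopHat and HTSeq, with no version. The 24 files without ethanol have the HTSeq layout, with counts per coding part and lines for reads on no feature and ambiguous reads. The 6 ethanol files were counted on exon features with featureCounts 1.6.3, per the file headers. The genome build is not given in the sources used here, and coordinates are those of the featureCounts files. Strand use in the HTSeq counting is not given either, so overlapping and antisense genes are uncertain. Parts of a gene were summed to 5207 genes in K. marxianus and 5320 in K. lactis, which all 15 files of a species share by ID. Reads on no feature, a mean of 4.71% in K. marxianus controls and 5.49% in K. lactis controls, and ambiguous reads stayed out of library sizes and tests. No feature ID was found in the reference gene table, so gene names came only from the IDs that carry one.

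Each species was fitted in edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test on all 15 libraries with group as the only term, after the filterByExpr filter and TMM scaling. The filter left 5098 genes of K. marxianus and 5124 of K. lactis. Tests were 2-sided, adjusted by Benjamini-Hochberg over the genes tested, and called at an adjusted p under 0.05. The biological coefficient of variation was 0.108 and 0.145, and TMM factors ran from 0.712 to 1.36 and 0.735 to 1.39. Printed CPM values of genes use TMM-scaled totals, and shares of a library use raw totals. Groups of genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 3 groups tested in K. marxianus or the 5 in K. lactis, with an estimated correlation and fry beside it. None of the group calls printed held with the estimated correlation.

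The gene lists fixed before the data were examined could not be used: of their 701 members the IDs name 1 in K. lactis, RPL39, and 0 in K. marxianus. The groups of genes by position, number of coding parts, overlap, ID type and tRNA were chosen after the files were seen and before their group results were. Of these, overlapping genes were lower in K. marxianus ethanol (125 of 223 lower, camera adjusted p = 2.43e-08, adjusted p = 0.0772 with an estimated correlation, with the 71 genes at 0 among the lower). By camera they passed in no other comparison, and the 33 tested ancestral-locus IDs of K. lactis passed in none. By fry, which sets a group against no other genes, overlapping genes also passed in K. lactis heat (adjusted p = 2.55e-05) and ethanol (5.41e-10). The ancestral-locus IDs passed fry in heat, MMS and caffeine (adjusted p = 0.00308, 0.000934 and 0.00217) and not in ethanol (0.32). No names pair the genes of the species, so the species-by-stress interactions, the correlations between species, the species difference at 28C and the tests of fixed lists were not run.

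The rule for named genes, also fixed beforehand, took those with an adjusted p under 0.05, at least a 2-fold change, at least 10 CPM in the higher group and all 3 stressed libraries on the same side of all 3 controls. Chance separates 10% of genes in either direction, and 62.5% to 81.2% of tested genes were separated across the 8 comparisons. Without names it allows 2 IDs per direction, those with the largest change. After the values were seen, IDs that overlap another gene or end in r were passed over. This changed picks in ethanol alone, where the unrestricted rule gives KM020B03850, KM020D02040, KM020C02050, KLLA0D17562r, KLLA0D17666r, KLLA0B07601g and KLLA0E12541g. K. lactis IDs that carry a gene name are given where they pass the same rule.

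The edgeR and DESeq2 steps were tested on simulated counts with 200 changed genes for each comparison, over 5098 or 5124 genes. Across the 8 simulated comparisons edgeR recovered 97% to 100% of 4-fold, 88.1% to 98.5% of 2-fold and 58.2% to 85.1% of 1.5-fold changes, with 3.24% to 8.2% false calls. DESeq2 1.42.0, an alternative, gave 6.15% to 17.4% false calls in the same data. The simulated groups shared 1 dispersion per gene, and far fewer genes changed than the 59.5% to 71.7% called in the real comparisons. These rates therefore do not carry over to the real calls. The first bound set for false calls, which covered both tools, was exceeded by DESeq2 and was then kept for edgeR alone.

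Alternatives were RLE scaling, DESeq2, no filter except a total above 0, fits of the 6 libraries compared or without ethanol, a 2-fold minimum, the replicate number as a block, and each replicate left out in turn. After the data were seen, fits without overlapping or multi-part genes and with all libraries thinned to the smallest total were added. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom from 8.7 to 1300, so none was counted as a repeat. Single values were compared by exact permutation with scipy 1.17.1. A floor of 3 counts per library was used where a library had 0, and floors cover counting error only. Genes near chromosome ends lie within 20 kb of the first base or of the last feature of a sequence over 500000 bases.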

Results

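Gene expression was measured by sequencing of poly(A)-captured RNA in the yeasts Kluyveromyces marxianus, strain Km31, and Kluyveromyces lactis, strain yLB72. Each species was grown without added stress at 28C, in heat at 39C, or with the alkylating agent methyl methanesulfonate (MMS), ethanol or caffeine. Each of the 10 groups held 3 biological replicates, which gave 30 libraries. Totals of gene counts, in units of 1e6, ran from 16.0 to 39.1 per library in the 12 K. marxianus libraries without ethanol and from 16.9 to 50.9 in the 12 of K. lactis. The ethanol libraries held 40.2 to 102.9 in K. marxianus and 39.0 to 94.4 in K. lactis. The ethanol files came from another counting program and another feature type than the rest, so every ethanol value below compares cultures and counting methods together, and the design cannot separate them. Any difference in library preparation or sequencing run that went with these files would be confounded in the same way. The balance of higher and lower calls depends on the scaling, so it is given below under TMM and RLE scaling, and an excess of either is not read as a response. The comparisons ask how each species' transcriptome differed between a stress and its own 28C control. The files do not pair most gene IDs with names, so at most 2 IDs that rose and 2 that fell are printed per comparison, without a function.

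In both species the first principal component set ethanol apart from the other conditions. It held 62.9% of the variance in K. marxianus and 41.5% in K. lactis. The components used all tested genes, including the 71 and 21 overlapping genes at or near 0 in ethanol, and were not recomputed without them. Over genes of at least 10 CPM that overlap no other gene, ethanol did not lie farthest from controls. The root mean square log2 distance there was 0.858 in ethanol against 0.959 in caffeine in K. marxianus. In K. lactis it was 0.818 in ethanol, the smallest of the 4 stresses. Caffeine lay farthest from the remaining groups on the second component in K. marxianus, which held 18.8%. In K. lactis, MMS replicate 3 lay between the other MMS libraries and the heat libraries.

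**Figure D1:**
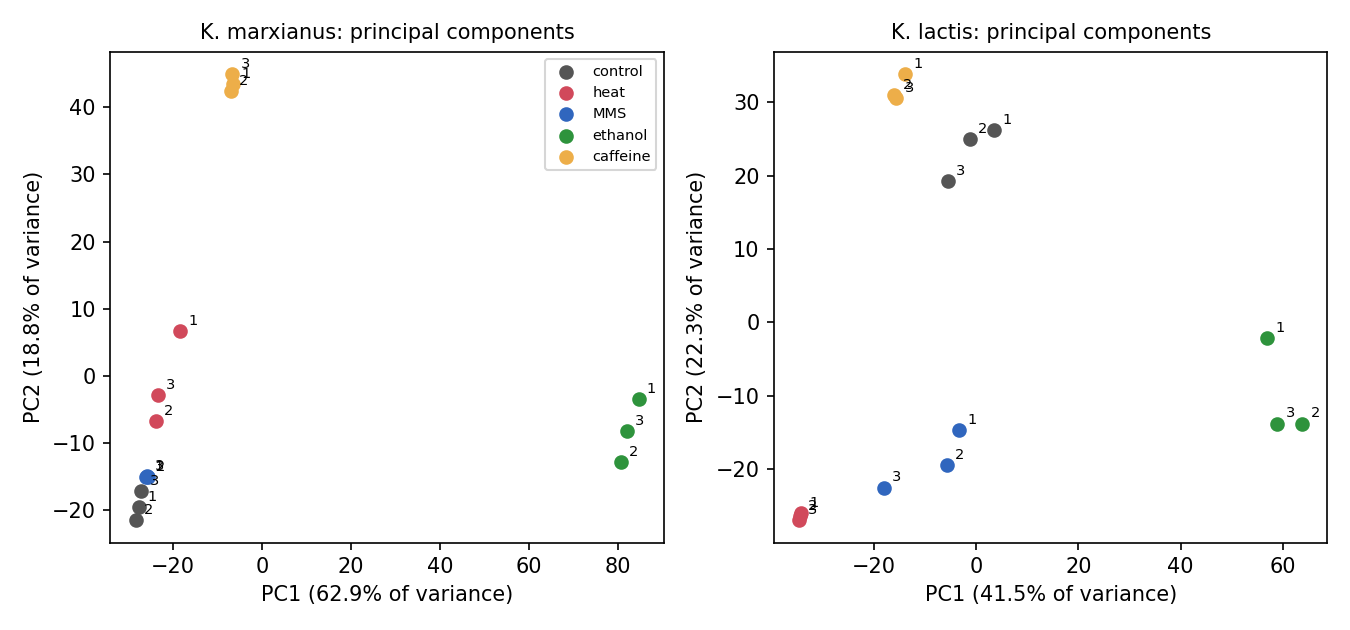
Principal components of log expression in K. marxianus (left) and K. lactis (right), with the share of variance on each axis; each point is 1 library, coloured by condition and numbered by replicate. The ethanol libraries lie alone at the right of both plots, on a component that holds 62.9% and 41.5% of the variance.

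The genes most abundant in control cultures lost much of their share under stress. The 10 most abundant genes of K. marxianus controls took 32.0% ± 1.53 (SD, n = 3) of gene counts in controls, 18.4% ± 3.52 in heat, 23.6% ± 0.367 in MMS, 7.21% ± 1.96 in ethanol and 2.98% ± 0.338 in caffeine. The corresponding 10 genes of K. lactis took 22.6% ± 1.5 in controls, 9.22% ± 0.601 in heat, 5.75% ± 0.566 in MMS, 14.2% ± 2.97 in ethanol and 7.74% ± 0.233 in caffeine. In all 8 comparisons, every stressed library lay below every control library, a separation that chance gives 10% of the time in either direction. The 2-sided exact permutation p was 0.1 in each, the smallest that 3 libraries against 3 allow, and 0.123 after Benjamini-Hochberg adjustment over 48 tests. These genes were picked for being high in the controls, so some fall is built into the choice.

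**Figure D2:**
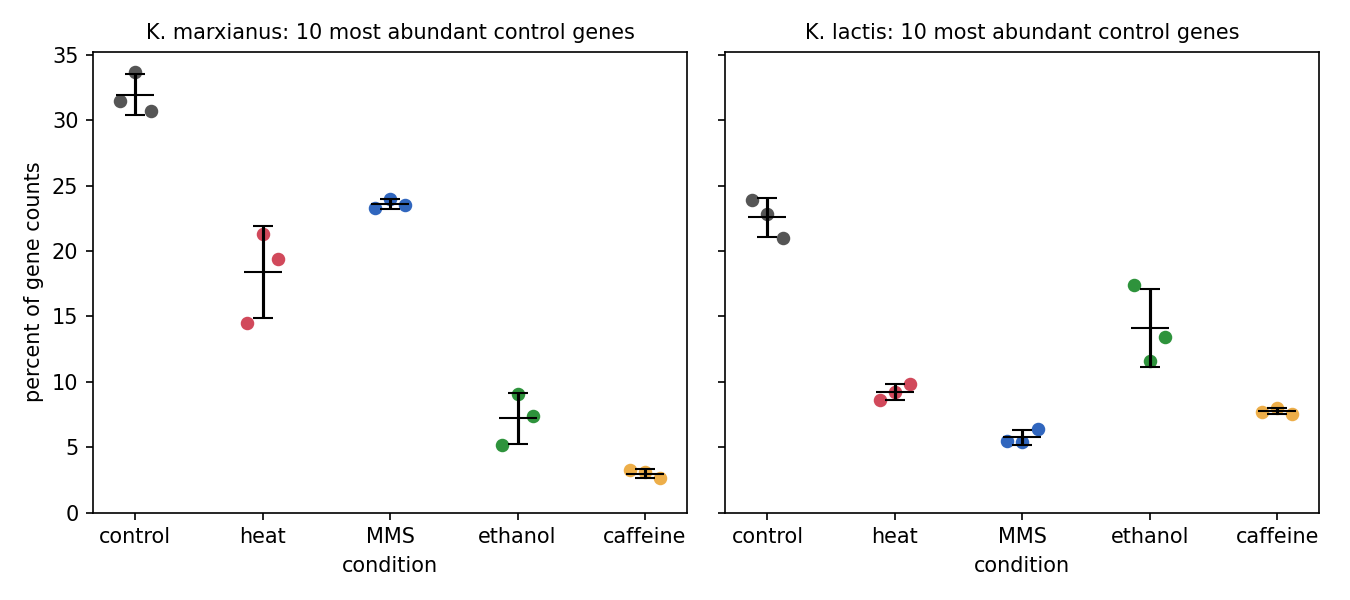
Share of gene counts, in percent, taken by the 10 most abundant control genes of each species; points are libraries and bars are means with SD (n = 3). All stressed libraries lie below the controls, down to a mean of 2.98% for K. marxianus in caffeine.

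Heat in K. marxianus raised KM020A01290 (chromosome 1, 233866 to 235047) 20.8-fold, from 48.6 ± 5.8 to 1010 ± 84.8 CPM (SD, n = 3; edgeR adjusted p = 5.16e-11). KM020A05770 (chromosome 1, 1152056 to 1153480) rose 10.6-fold to 95.5 ± 10.6 CPM. The deepest falls were 16.5-fold in KM020A08410 (chromosome 1, 1701866 to 1703341), from 130 ± 6.17 to 7.88 ± 0.159 CPM, and KM020D06580 (chromosome 4, 1407275 to 1408309) with a log2 change of -3.59 ± 0.23 (SE derived from the quasi-likelihood F statistic), from 154 ± 22.3 to 12.8 ± 1.45 CPM. Of 5098 genes tested, 1531 were higher and 1504 lower (1493 and 1545 with RLE scaling), and 259 and 276 of these changed at least 2-fold. The 97 tested genes within 20 kb of a chromosome end passed no test of a shared direction (34 rose, 33 fell, median log2 change 0.00, camera adjusted p = 0.994). Of them 22.7% changed at least 2-fold, against 10.5% of all tested genes. This was not particular to heat: the shares were 21.6% against 10.5% in MMS, 30.9% against 21% in ethanol and 36.1% against 21.5% in caffeine. The K. lactis end genes also exceeded all tested genes in each stress, as in heat with 42.9% against 25.4%. These excesses were not tested.

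MMS in K. marxianus raised KM020A00220 (chromosome 1, 30157 to 30819) 13.7-fold to 343 ± 7.64 CPM (SD, n = 3; edgeR adjusted p = 7.36e-09). KM020G01730 (chromosome 7, 339008 to 342159) rose 10.8-fold to 1820 ± 45.9 CPM. KM020E05570 (chromosome 5, 1129085 to 1130482) fell 14.6-fold, from 41.9 ± 6.93 to 2.9 ± 0.298 CPM, and KM020A02230 (chromosome 1, 439872 to 442570) fell 13.0-fold, from 215 ± 28.3 to 16.5 ± 0.17 CPM. In all, 1590 genes were higher and 1583 lower (1435 and 1716 with RLE scaling), with 287 and 250 changed at least 2-fold.

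In ethanol, KM020A08190 of K. marxianus (chromosome 1, 1659365 to 1665397) stood 398-fold higher, at 3150 ± 70.5 CPM against 7.91 ± 0.54 in controls (SD, n = 3; edgeR adjusted p = 3.82e-16). It lay between 4.34 and 9.55 CPM in all 12 libraries without ethanol, so this difference coincides with the change of counting method. KM020G03070 (chromosome 7, 620003 to 621223) was 23.3-fold higher at 19.5 ± 6.17 CPM, and it was also 40.4-fold higher in caffeine, which was counted as the controls were. KM020D01250 (chromosome 4, 243520 to 244566) was 83.8-fold lower, at 406 ± 74.0 CPM against 34000 ± 3580, and KM020B05990 (chromosome 2, 1207843 to 1208655) was 34.6-fold lower. In total 1919 genes were higher and 1738 lower (1794 and 1853 with RLE scaling), with 569 and 503 changed at least 2-fold. Of 141 tested genes in more than 1 coding part, 77 were higher and 26 lower (median log2 change 0.28; camera adjusted p = 0.00166, adjusted p = 0.475 with an estimated correlation). The lower genes include 71 with no count in any ethanol library and over 10 CPM in every other library, and all 71 overlap another gene in the annotation. Without them 1667 genes were lower, 432 at least 2-fold. The rest of the 125 overlapping genes called lower stay in that count.

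Caffeine in K. marxianus raised KM020H02340 (chromosome 8, 497637 to 498674) 82.5-fold, from 0.946 ± 0.395 to 78.8 ± 6.51 CPM (SD, n = 3; edgeR adjusted p = 6.03e-10). KM020G03070 rose 40.4-fold to 33.8 ± 2.51 CPM. KM020D02440 (chromosome 4, 527007 to 528053) fell 150-fold, from 36800 ± 2420 to 246 ± 73.4 CPM, and KM020C00500 (chromosome 3, 94512 to 96370) fell 113-fold, from 1020 ± 104 to 9.0 ± 0.485 CPM. In total 2016 genes were higher and 1635 lower (1863 and 1804 with RLE scaling), and 614 and 482 changed at least 2-fold.

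Heat in K. lactis raised KLLA0E24883g (chromosome 5, 2205689 to 2207464) 38.5-fold, from 8.48 ± 0.914 to 327 ± 52.0 CPM (SD, n = 3; edgeR adjusted p = 2.3e-09). KLLA0C07777g (chromosome 3, 682962 to 684506) rose 33.1-fold to 670 ± 93.6 CPM; its log2 change was 5.05, and 5.79 without control replicate 3. KLLA0C19338g (chromosome 3, 1729569 to 1730978) fell 94.3-fold, from 2150 ± 678 to 22.8 ± 1.28 CPM, and KLLA0E14015g (chromosome 5, 1242786 to 1243832) fell 50.0-fold. The ID that carries the name MEI4, in baker's yeast a gene for meiotic DNA breaks, rose 2.88-fold from 4.02 ± 0.639 to 11.6 ± 0.816 CPM (adjusted p = 2.83e-06). The ID with the name YER053C-A rose 4.44-fold to 185 ± 12.7 CPM. Genes near chromosome ends fell as a group: 45 of the 70 tested within 20 kb of an end fell and 6 rose, with a median log2 change of -0.70 (camera adjusted p = 0.000397, adjusted p = 0.748 with an estimated correlation). Of 44 tested tRNA genes, 17 rose and 6 fell. The group did not pass camera (adjusted p = 0.219), while fry gave an adjusted p of 0.0204. Reads on no feature took 6.61% ± 0.502 in heat against 5.49% ± 0.0351 in controls. In all, 1653 genes were higher and 1983 lower (1827 and 1812 with RLE scaling), with 605 and 695 changed at least 2-fold.

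**Figure D3:**
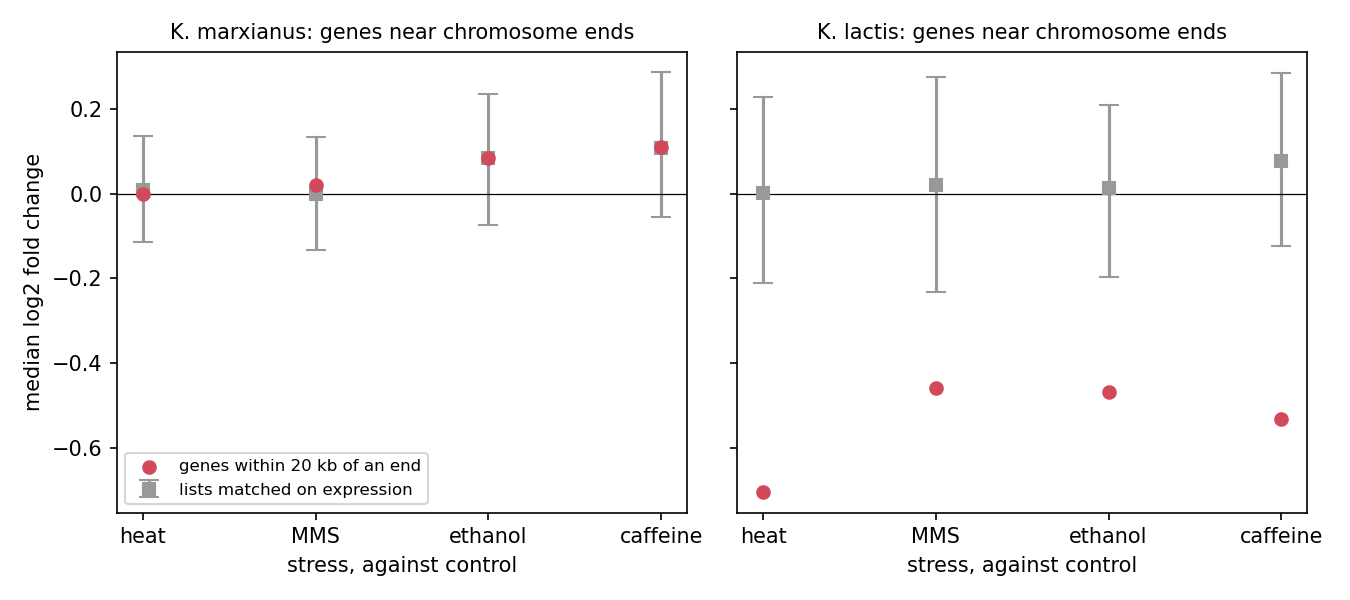
Median log2 change of genes within 20 kb of a chromosome end (red) and of lists matched on mean expression (grey, with the range of the middle 95% of 10000 lists) in K. marxianus (left) and K. lactis (right). The K. lactis medians lie below the matched lists in all 4 stresses, lowest in heat at -0.70. The lists treat genes as independent, so the grey ranges are too narrow for genes that change together.

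MMS in K. lactis lowered the counts of tRNA genes, whose mature products carry no poly(A) tail. Of 44 tested, 26 fell and 0 rose, with a median log2 change of -2.47 (camera adjusted p = 0.000359, adjusted p = 0.205 with an estimated correlation). All tRNA genes together took 7.51 ± 0.697 CPM (of raw totals) in MMS against 23.9 ± 1.12 in controls (SD, n = 3). These rest on 135, 177 and 139 counts over 162 tRNA genes in the MMS libraries, against about 578 to 1210 in controls. Single tRNA genes therefore lie near the counting floor in MMS. Reads on no feature moved the same way, at 5.0% ± 0.286 against 5.49% ± 0.0351 in controls, and every MMS library lay below every control (exact permutation p = 0.1, 0.123 after adjustment). KLLA0E16897g (chromosome 5, 1500700 to 1503177) rose 15.8-fold to 559 ± 152 CPM (edgeR adjusted p = 3.83e-05). KLLA0C00440g (chromosome 3, 32008 to 33141) stood 39.6-fold higher on average, at 867, 791 and 33.7 CPM in replicates 1, 2 and 3 against 14.2 ± 1.1 in controls. KLLA0C19338g fell 120-fold to 17.9 ± 3.27 CPM, and KLLA0C11913g (chromosome 3, 1024233 to 1025822) fell 26.0-fold to 27.8 ± 5.72 CPM. YER053C-A rose 3.1-fold. PMP1, in baker's yeast a small regulator of the plasma membrane proton pump, fell 2.25-fold to 337 ± 100 CPM. VMA9, named for a vacuolar proton pump subunit, fell 2.13-fold, in a gene that overlaps another. RPL39, named for a protein of the large ribosomal subunit, fell 3.31-fold from 350 ± 69.6 to 106 ± 104 CPM (edgeR adjusted p = 0.0194). The RPL39 call was lost without MMS replicate 1, MMS replicate 2 or control replicate 2 and in a fit of the 6 libraries alone (adjusted p = 0.0516 to 0.0828), and its log2 change of -1.73 became -2.93 without MMS replicate 3. Genes near chromosome ends also fell in MMS, measured against the same controls as in heat: 38 of 70 fell and 14 rose (median -0.46, camera adjusted p = 0.0114, adjusted p = 0.518 with an estimated correlation, and 0.0688 without MMS replicate 3). Genes in more than 1 coding part fell in 102 of 206 cases and rose in 35 (adjusted p = 0.00169, adjusted p = 0.518 with an estimated correlation). The MMS libraries disagree on these genes' share of counts, which was 3.35%, 3.15% and 6.1% in replicates 1, 2 and 3 against 4.23% to 4.88% in controls (exact permutation p = 0.8). Without replicate 3 the camera adjusted p was 0.000168. In all, 1828 genes were higher and 1837 lower (1857 and 1809 with RLE scaling), with 510 and 721 changed at least 2-fold.

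**Figure D4:**
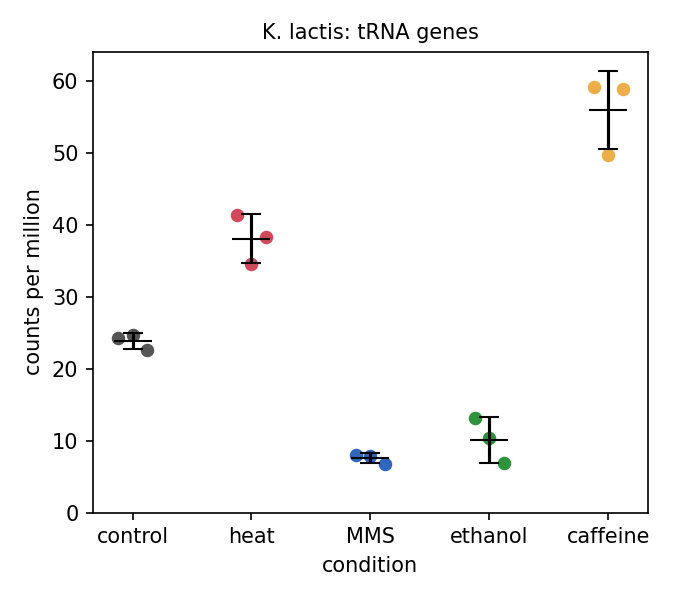
CPM on all annotated tRNA genes of K. lactis by condition; points are libraries and bars are means with SD (n = 3). MMS and ethanol lie below the controls at 7.51 and 10.1, and heat and caffeine above them at 38.1 and 56.0.

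In ethanol, K. lactis had KLLA0D04181g (chromosome 4, 355576 to 360564) 54.8-fold higher at 28.4 ± 2.05 CPM and KLLA0B00451g (chromosome 2, 31822 to 32982) 53.6-fold higher at 835 ± 130 CPM (SD, n = 3; edgeR adjusted p = 2.81e-13 for the second). KLLA0D00187g (chromosome 4, 7837 to 8277) was 19.5-fold lower and KLLA0D12738g (chromosome 4, 1086914 to 1090000) 13.8-fold lower. Of the tRNA genes, 26 were lower and 1 higher (median log2 change -2.20; camera adjusted p = 3.34e-05, adjusted p = 0.124 with an estimated correlation). The ethanol libraries held 515, 982 and 311 tRNA counts in total. PMP1 was 2.45-fold lower at 309 ± 89.8 CPM, and VMA9, which overlaps another gene, was 2.19-fold higher. RPL39 was 2.81-fold lower (adjusted p = 0.0414), a call lost without any 1 of the 3 controls, ethanol replicate 2 or ethanol replicate 3 (adjusted p = 0.0542 to 0.126); its log2 change of -1.49 became -2.13 without ethanol replicate 1. Near chromosome ends 37 genes were lower and 17 higher (median -0.47; adjusted p = 0.0319, adjusted p = 0.594 with an estimated correlation). That call was lost without control replicate 1, ethanol replicate 2 or ethanol replicate 3, with adjusted p from 0.0548 to 0.0888. In all, 1697 genes were higher and 1657 lower (1597 and 1735 with RLE scaling), and 401 and 559 of these changed at least 2-fold. The lower genes include 21 with at most 3 counts in each ethanol library and over 10 CPM in every other library, all of which overlap another gene. Without them 1636 genes were lower, 538 at least 2-fold, with other overlapping genes kept.

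Caffeine in K. lactis raised KLLA0F25520g (chromosome 6, 2370884 to 2372155) 164-fold, from 2.93 ± 1.07 to 496 ± 56.5 CPM (SD, n = 3; edgeR adjusted p = 5.62e-10), and KLLA0E24883g 93.9-fold to 798 ± 24.0 CPM. KLLA0C19338g fell 108-fold to 19.9 ± 0.92 CPM, and KLLA0D06083g (chromosome 4, 521215 to 521565) fell 35.6-fold. MFA1, named for a mating pheromone precursor, rose 3.86-fold from 4.76 ± 0.692 to 18.6 ± 2.06 CPM, and YER053C-A rose 3.41-fold. Poly(A)-captured counts of the small nucleolar RNA snR30, needed for ribosomal RNA processing in baker's yeast, fell 3.6-fold. They went from 19.9 ± 1.85 to 5.51 ± 1.08 CPM (edgeR adjusted p = 1.1e-06), and the total level of this RNA was not measured. Of the tRNA genes, 17 rose and 3 fell (median log2 change 0.92; camera adjusted p = 0.041, adjusted p = 0.601 with an estimated correlation). The tRNA call was lost without caffeine replicate 1 or 3 or any 1 of the 3 controls (adjusted p from 0.0566 to 0.0862), and with RLE scaling (0.0543) or no count filter (0.338). Reads on no feature took 7.61% ± 0.59 in caffeine against 5.49% ± 0.0351 in controls. Near chromosome ends 39 genes fell and 13 rose (median -0.53; adjusted p = 0.0311, adjusted p = 0.601 with an estimated correlation, and 0.0563 without caffeine replicate 3 or 0.0506 without control replicate 1). In all, 1616 genes were higher and 1598 lower (1673 and 1548 with RLE scaling), with 442 and 461 changed at least 2-fold.

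**Figure D5:**
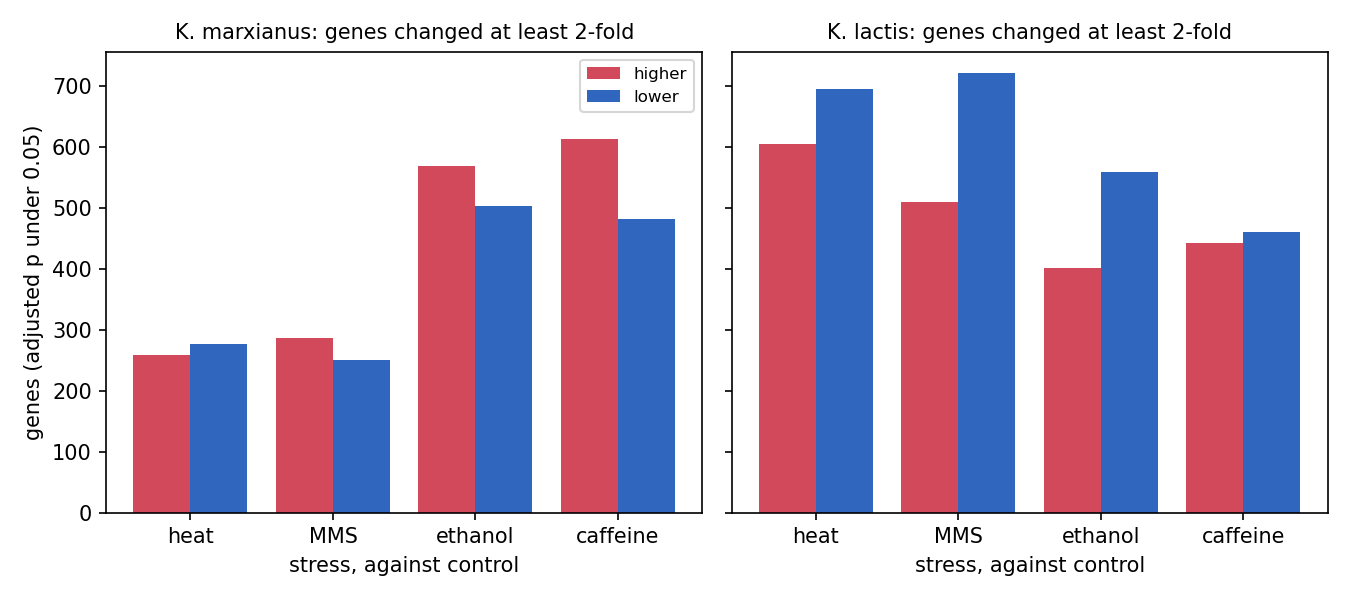
Genes changed at least 2-fold at an edgeR adjusted p under 0.05, higher (red) and lower (blue), for each stress against control in K. marxianus (left) and K. lactis (right). Counts range from 250 lower genes in K. marxianus MMS to 721 lower genes in K. lactis MMS, and the ethanol bars include the 71 and 21 overlapping genes at or near 0.

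Many genes moved the same way in all 4 stresses. In K. marxianus 1027 genes did, 521 higher and 506 lower, where independent lists would share 122, and 74 of them changed at least 2-fold in each stress. In K. lactis 762 genes did, 308 higher and 454 lower, against 133 for independent lists, and 113 changed at least 2-fold. Unchanged groups simulated against the same controls shared 0 genes in each of 20 simulations in both species, which is chance with no effect. The simulated value leaves out the effects and the independent lists leave out the shared controls. More genes were called in opposite directions in at least 1 pair of stresses, 1183 in K. marxianus and 1786 in K. lactis. Without the overlapping genes at or near 0 in ethanol, and with other overlapping genes kept, 1016 and 759 genes moved the same way in all 4 stresses. The 3 controls of a species were not split, since 1 part would keep a single library, so part of the excess may come from the controls that the comparisons share. Without ethanol, 1214 and 1316 genes moved the same way in the remaining 3 stresses.

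Ethanol and caffeine gave the most similar log2 changes in K. marxianus, with a correlation across 4619 genes of 0.794 (mean of 0.509 in 20 simulations of unchanged groups) and a covariance of 0.658 (simulated 0.00861). The K. marxianus pairs with MMS had the lowest correlations: 0.475 with heat (simulated 0.495), 0.424 with ethanol (simulated 0.506) and 0.391 with caffeine (simulated 0.502). Their covariances were 0.19, 0.237 and 0.245 (simulated 0.00855, 0.00859 and 0.00861). In K. lactis, heat and MMS correlated at 0.612 across 4778 genes (simulated 0.5), with a covariance of 0.547 (simulated 0.0142), and MMS and caffeine at 0.591 (simulated 0.502), with a covariance of 0.48 (simulated 0.0143). Their order rests on MMS replicate 3, which lay toward heat: without it the correlations were 0.506 for heat and MMS, 0.548 for MMS and ethanol and 0.564 for MMS and caffeine. Heat and ethanol had the lowest correlation, 0.163 (simulated 0.499), with a covariance of 0.124 (simulated 0.0141), and 1048 genes were called in opposite directions in that pair. The simulated correlations come from noise around shared controls alone, so the covariances are the closer comparison. These correlations run across genes, which are not independent replicates.

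The size of the response was set side by side between the species as the root mean square (RMS) log2 distance of each library from the controls, over 4501 genes in K. marxianus and 4648 in K. lactis. Heat gave 0.629 ± 0.0682 in K. marxianus and 0.933 ± 0.00313 in K. lactis, and MMS gave 0.64 ± 0.0128 and 0.966 ± 0.0256 (SD, n = 3). Caffeine gave 0.959 ± 0.00953 and 0.848 ± 0.0106, and ethanol 0.858 ± 0.0721 and 0.818 ± 0.1. The 2-sided exact permutation p was 0.1 for heat, MMS and caffeine, the smallest possible, and 0.6 for ethanol. After adjustment over 4 tests these exact p values were 0.133 and 0.6, so no difference in size between the species passed a 0.05 threshold. The genes behind the distances are not matched between the species.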

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

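The tests in this part of lost transcripts, of genes wholly inside another gene and of K. lactis MMS replicate 3 were chosen only after the result was seen.

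Reads on no feature took a larger share than in controls in 4 groups outside ethanol. They made up 5.91% in K. marxianus heat and 7.34% in K. marxianus caffeine against 4.71% in controls, and 6.61% in K. lactis heat and 7.61% in K. lactis caffeine against 5.49%. In K. lactis MMS they took less, 5.0%, with every library below every control. Ambiguous reads also lay above controls in every library of 3 groups, with 1.42% in K. marxianus caffeine against 1.14%, and 3.44% in K. lactis heat and 2.43% in K. lactis caffeine against 2.1%.

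The share of counts on genes near chromosome ends was above all controls in every K. marxianus library and below all controls in every K. lactis library of 3 stresses. The K. lactis change minus the K. marxianus change was -0.607 percentage points in heat (0.231 and -0.375), -0.615 in MMS (0.21 and -0.405) and -0.948 in caffeine (0.559 and -0.389). In ethanol the K. lactis share was 1.05% against 1.07%, not below all controls. The difference between the species was not tested. The K. marxianus genes passed no test of a shared direction, with median log2 changes of 0.00 in heat, 0.02 in MMS, 0.08 in ethanol and 0.11 in caffeine, inside the range of matched lists. The 10 most abundant control genes lost share in the same libraries, which by arithmetic lifts the share of other genes.

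The fall of K. lactis genes near chromosome ends was set against lists matched on mean expression. The 4 stresses share the same 3 controls, in which these genes took 1.17%, 1.07% and 0.97% of counts. The falls are therefore not independent of each other. Low expression of genes near chromosome ends is argued against, since of 10000 such lists 0% had a median as low in heat, 0.01% in MMS, 0% in ethanol and 0% in caffeine. The lists treat genes as independent, while the end genes had an estimated correlation of 0.143 to 0.149. With it the camera adjusted p ran from 0.518 to 0.748, so these shares overstate how unusual the fall was. By fry, which sets the end genes against no other genes, the adjusted p ran from 5.08e-06 in heat to 9e-04 in caffeine. Reads shared between related genes near the ends, and a biological response to stress, both stay open and were not tested.

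Genes listed at 0 in ethanol, with over 10 CPM in every other library, numbered 71 in K. marxianus and 21 in K. lactis, the latter with at most 3 counts per library, and all 92 overlap another gene, against 3.7% of all genes. KM020D02040 was at least 155000-fold lower than its control mean of 11600 CPM of raw totals by the floor of 3 counts per library, and KLLA0B07601g at least 6220-fold lower. That share of 100% argues against loss of the transcripts in ethanol. A count of genes wholly inside another gene, where reads inside another gene's exon left uncounted would empty every member, found 93 of 93, or 100%, at no more than 3 counts. The planned test of overlapping features in the ethanol annotation stays undecided: across overlapping genes the ethanol change fell with the covered share, at a Spearman rho of -0.673 in K. marxianus and -0.538 in K. lactis, but rho in K. lactis caffeine was -0.257, beyond the 0.2 set beforehand for stresses counted without featureCounts.

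In K. lactis, MMS replicate 3 lay at an RMS log2 distance of 0.487 from the mean of the other MMS libraries, which were 0.174 apart. Its deviation correlated at 0.776 across 4648 genes with the difference of heat from MMS. Both are differences from the same MMS libraries, which alone can give a correlation above 0. With the differences of control, caffeine and ethanol from MMS it correlated at 0.329, 0.374 and 0.11. A heat library under a wrong label is argued against by its distance to the heat mean, 5.27 times the largest among heat libraries. Lower depth is argued against by its total, 20.7 in units of 1e6, between 16.9 and 22.6 in replicates 1 and 2. Its spread stayed 2.78 times as large after thinning, which could hardly come out otherwise for a library that was not the shallowest. RNA or reads of a heat library mixed in would give 1 heat share throughout. Genes higher in heat gave 0.489, genes lower in heat 0.529 and tRNA genes -0.0398, a range of 0.569. The first 2 values are medians, which lay close, but single genes varied. Their quartiles were 0.168 and 0.569 for genes higher in heat, and 0.413 and 0.682 for genes lower in heat. The spread that a true mixture would give single genes was not measured. Ambiguous reads lay toward heat (mean 3.44%), at 3.02% against 1.75% and 1.69% in replicates 1 and 2. The range was 0.464 and 0.229 for replicates 1 and 2, whose reference contains replicate 3. A wide range alone therefore does not tell against mixing. The tRNA value, from 139 counts, argues against reads of a sequenced heat library mixed in. It cannot judge RNA mixed before poly(A) capture, since mature tRNAs carry no tail and need not follow the mixing share. Such mixing and a different state of this culture stay open and were not tested.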

How the results depend on the processing

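Fits without overlapping or multi-part genes, fits on thinned counts, and fits without K. lactis MMS replicate 3 or K. marxianus heat replicate 1 in results of other groups or of stress pairs were chosen after the data were seen. Of 150 counts of called genes under an alternative, 139 lay within 1.5 times the reported count. Of the others, 10 came from the 2-fold minimum, which by construction counts fewer genes: 535, 537, 1072 and 1096 in K. marxianus heat, MMS, ethanol and caffeine, 1300, 1231, 960 and 903 in K. lactis, and 74 and 113 for all 4 stresses. The last was K. lactis without ethanol, where 1316 genes moved the same way in 3 stresses, a condition that asks less. Leaving out 1 replicate gave 2721 to 3045 calls in K. marxianus heat and 3371 to 3775 in K. lactis MMS. Of 643 fold changes of named genes, 0 changed sign and 9 lost the call, all of RPL39, whose cause was not tested. Of 192 group tests, 14 lost and 3 gained a call. The gained calls were K. marxianus genes in more than 1 coding part without caffeine replicate 2 (adjusted p = 0.0158) or, in heat, without control replicate 1 (0.0355), and K. lactis tRNA genes in heat with no filter (0.00505). The tRNA call in K. lactis caffeine was also lost without overlapping or multi-part genes (0.074). Without K. lactis MMS replicate 3, heat and MMS no longer had the highest correlation of the K. lactis stress pairs (0.506 against 0.564 for MMS and caffeine). RLE scaling moved no median by over 0.1 but turned the balance of higher and lower calls in all comparisons except caffeine. In K. marxianus, 1531 and 1504 became 1493 and 1545 in heat, 1590 and 1583 became 1435 and 1716 in MMS, and 1919 and 1738 became 1794 and 1853 in ethanol. In K. lactis, 1653 and 1983 became 1827 and 1812 in heat (DESeq2 1903 and 1875), 1828 and 1837 became 1857 and 1809 in MMS, and 1697 and 1657 became 1597 and 1735 in ethanol. The excess of higher calls in K. marxianus caffeine, 2016 and 1635, shrank to 1863 and 1804.

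The libraries were not treated as paired, since the labels give the replicate numbers no shared batch or day and not every same-number pair correlated over 0.1: correlations of deviations ran from -0.277 to 0.472 in K. marxianus and -0.229 to 0.56 in K. lactis, and 11 and 13 of 30 pairs were over 0.1. In each species 10 of 15 libraries correlated best with their own number, a hint from the data and not the design, so pairing is not shown to be absent. With the number as a block, calls came to 3075, 3232, 3686, 3688 and 1055 (all 4 stresses) in K. marxianus and 3610, 3719, 3342, 3256 and 754 in K. lactis.

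Splits of the 6 libraries of a comparison number 10, too few for a share under 0.05, and 1 of 10, the real one, called the most in each. The real split called 2660, 3584, 3664 and 3809 genes in K. marxianus and 4014, 3339, 2931 and 3715 in K. lactis, and the highest other split 0. The interactions, correlations and 28C difference between species and the tests of fixed lists were not run.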

Other observations

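Neighbouring genes changed together more when they were transcribed away from each other. Among K. marxianus neighbours, the rank correlation of log2 changes across 1102 divergent pairs was 0.161 in heat, 0.256 in MMS, 0.207 in ethanol and 0.178 in caffeine. Across 1144 convergent pairs it was 0.0235, 0.116, 0.0447 and 0.0246. In K. lactis, 1177 divergent pairs gave 0.297, 0.263, 0.203 and 0.264, and 1217 convergent pairs gave 0.0591, 0.0841, 0.0474 and -0.00135. Neighbours on the same strand gave 0.145, 0.116, 0.146 and 0.168 across 1833 pairs in K. marxianus and 0.118, 0.13, 0.113 and 0.0832 across 1854 pairs in K. lactis.

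A shared promoter region between divergent genes may account for this, as a hypothesis. It predicts a higher correlation in divergent than in convergent pairs, which held in 4 of 4 stresses in K. marxianus and in 4 of 4 in K. lactis, with permutation p values from 0.0001, the smallest 10000 permutations can give, to 0.0014 (adjusted over 8 tests, 0.000267 to 0.0014). The same-strand values, close to the divergent ones in K. marxianus heat and caffeine, are not explained by it and were not tested. Pairs are not independent replicates, the 4 stresses share their controls, and the median gap also differed, at 506 against 160 bases in K. marxianus and 587 against 184 in K. lactis.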
